A study of Homo sapiens with 4 samples.

How the data were processed

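Total RNA from 4 cultures of established human glioma cells was measured, each on 1 Affymetrix expression array. The cultures were U251 and LN-319 cells, each carrying either a control lentivirus that expresses GFP or a lentivirus that expresses a short hairpin RNA against the circular RNA of the SHPRH gene. Cells were selected with puromycin after infection, per the labels' protocols. The design therefore held 1 array per cell line and virus, and the cell line paired the arrays: each sh-Circ-SHPRH array was set against the GFP control array of its own line. The labels do not say whether any culture was repeated. P-values of the gene-by-gene test of the virus therefore measure the spread between the responses of the lines. They do not measure the spread between cultures of 1 line. P-values of the main test of gene lists and of shuffled gene order compare genes with other genes and measure neither spread.

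The values were used as deposited. The authors deposited log2 values for 54675 probe sets, with 1 column per array. Both RMA and MAS5 are named in the submitters' processing notes. Which of these made the values, and in which version, is not given in the sources used here. The scale was read from the values themselves, which ran from 0.52 to 13.7 and are levels, not ratios. The array medians were 4.59 in the U251 GFP control, 4.57 in the U251 sh-Circ-SHPRH, 4.57 in the LN-319 GFP control and 4.57 in the LN-319 sh-Circ-SHPRH array. Sorted values of any pair of arrays differed by at most 0.15, so the arrays had been brought to nearly the same distribution before deposit. Scanner files were not analysed here. For arrays no sequencing depth applies, and the number of arrays limits the precision.

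Probe sets were named through the platform's annotation. After 62 control probe sets had been left out, 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none in that table. A probe set with several symbols named no gene. Of the probe sets with 1 symbol, 41037 had a gene identifier in the RefSeq gene table of assembly GRCh38.p14, and that table changed 0 symbols. The table was used for names and for the order of neighbouring genes. No coordinates are printed, because the array files name no genome build. Each of the 19775 genes was represented by its probe set with the highest mean over the 4 arrays. A gene was tested if that probe set was at or above the array's own median on at least 1 array, which left 13471 genes.

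Differences are sh-Circ-SHPRH minus GFP control on the log2 scale. The test of a change shared by both lines used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 4 arrays, the virus as the contrast and the cell line as a block. The fit had 1 residual degree of freedom and 3 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The same fit gave the differences between the lines. Within 1 line a difference has no replicate check, so genes at least 2-fold higher or lower were counted by size and no p-value was given. The overlap of such counts was set beside the number that independent lists of those sizes would share.

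The test was checked on simulated data built on the levels of the 13471 genes, with spreads drawn from the prior of the fit. In that simulation of the shared comparison, 75.7% of 70 genes changed 2-fold were called, as were 98.5% of 65 genes changed 4-fold and 100% of 65 genes changed 16-fold. There were 12 false calls among the unchanged genes. All changed genes were simulated together, each with the same change in both lines. Many true changes make the adjusted threshold easier to reach. The rates therefore do not hold for a few changed genes or for changes that differ between the lines.

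A set of 29 gene lists was fixed before the data were examined, as were the tests, the rule for naming genes and most alternatives. The lists cover the cell cycle, the post-replication repair that SHPRH belongs to, signalling and stress pathways, metabolism, glial identity and markers of other cell types. They were tested with camera at a preset correlation of 0.01, adjusted over the lists. For each line, the median of a list was also placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. The camera test was repeated with an estimated correlation, which rests on 1 residual degree of freedom and reached 1 for the interferon list, and with fry, which asks whether a list moves on balance in 1 direction. With 1 residual degree of freedom the estimated-correlation test and fry can hardly call any list. A call lost in either does not decide against a list.

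The rule for named genes was as follows. SHPRH, PCNA and DTL are always given. For the shared comparison, the 12 higher and 12 lower genes with the largest smaller-of-the-lines difference of 1 sign are named, whether or not they pass the test. The 8 largest differences in each direction are named within each line, the 4 largest opposite differences in each orientation, the 6 largest differences between the lines in each direction, and up to 4 members of each list described. Sex-specific genes, and placeholder symbols such as LOC, LINC and KIAA numbers and open reading frames, were passed over for the next gene. That LINC numbers count as placeholders was decided after the data were examined. Genes named outside this rule are said to have been chosen after their values were seen.

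The alternatives set before the data were examined were quantile normalization, centring each array on its median, no filter, a filter at the 75th percentile, the median of all probe sets of a gene, leaving out probe sets whose identifiers end in _x_at, log2(linear value + 64), leaving out each line, leaving out the line block, a trended and robust prior, a 1.5-fold threshold, and the other list tests. Subtracting the differences of neighbouring genes and leaving out the interferon list were added after the data were seen, as were the values by chromosome region. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

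The circular RNA itself was not analysed here, and no value is given for it. Some list members had no probe set with a single symbol in the annotation used and were left out of the list values.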

Results

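Gene expression was measured in 2 human glioma cell lines, U251 and LN-319, with stable lentiviral expression of either GFP or a short hairpin RNA against circ-SHPRH, a circular RNA made from exons of SHPRH. The study asked which genes the circular RNA regulates. There were 4 arrays, 1 for each combination of line and virus. Over all probe sets the arrays of 1 line correlated at r = 0.995 in U251 and r = 0.996 in LN-319, and arrays of different lines at r = 0.938. The 3' minus 5' signal of GAPDH, a sign of RNA integrity, was 0.22 and 0.29 log2 on the U251 control and sh-Circ-SHPRH arrays. It was 0.41 and 0.57 log2 on the LN-319 control and sh-Circ-SHPRH arrays. For ACTB the signal was larger, at 3.13 and 3.14 log2 in U251 and 3.94 and 4.17 log2 in LN-319, in the same order. Both signs were thus higher in LN-319 than in U251. No line had a second array of the same virus, so every within-line value below is a difference between 1 array and 1 array.

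The host gene of the circular RNA, SHPRH, encodes a ubiquitin ligase that acts on PCNA in post-replication repair. Its probe set read 6.48 log2 in the U251 control and 6.78 in the U251 sh-Circ-SHPRH array, a difference of 0.30. In LN-319 the levels were 6.60 and 6.56, a difference of -0.04, and the limma test over both lines gave an adjusted p = 0.918. The position of this probe set relative to the exons in the circle is not given in the sources used here, so it does not check the knockdown or the labels. PCNA, the replication clamp, differed by 0.07 in U251 and -0.06 in LN-319. DTL, which targets a ubiquitin ligase to PCNA-bound proteins, differed by -0.05 and 0.05. The 27 tested genes of the list for PCNA ubiquitination and post-replication repair had a median difference of 0.02 in U251 and 0.01 in LN-319. Its members with the largest mean differences were SPRTN, a protease for DNA-protein crosslinks (0.49 and 0.26), and CUL4A, a cullin scaffold (0.36 and 0.14). The list did not pass the camera test (adjusted p = 0.415).

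The first comparison asked which genes differed between sh-Circ-SHPRH and GFP control in the same way in both lines. Genes of hypoxia and glycolysis were lower in both: the 27 tested members had a median difference of -0.16 in U251 and -0.07 in LN-319, and 18 of them were lower in both lines. NDRG1, a hypoxia-induced gene, had the largest mean difference of this list at -0.73 ± 0.10 (limma's moderated SE, which borrows from the spread of all genes, n = 2 lines). It was followed by DDIT4, an inhibitor of mTORC1 signalling, at -0.61 ± 0.15, by the glycolytic regulator PFKFB4 at -0.41 ± 0.09 and by the angiogenic factor VEGFA at -0.33 ± 0.10. The glucose transporter gene SLC2A3, chosen after its values were seen, went the other way and was 0.30 and 0.26 higher. Over both lines this list passed camera with an adjusted p = 5.77e-06. That call was lost with an adjusted p = 0.832 with an estimated correlation.

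Metallothioneins, small metal-binding proteins, were also lower. Of 8 tested genes 7 were lower in both lines, with medians of -0.34 in U251 and -0.22 in LN-319. MT1E differed by -0.67 in U251 and -0.24 in LN-319, and MT1X by -0.44 and -0.34. MT1F and MT1G differed by -0.41 and -0.39 in U251 and by -0.29 and -0.25 in LN-319. The list passed camera (adjusted p = 4.89e-05), with an adjusted p = 0.832 with an estimated correlation. However, 6 of the 8 genes were read by _x_at probe sets, which can detect several family members. Without such probe sets 2 genes were left, MT1M and MT3, and the adjusted p was 0.868.

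Genes of the unfolded protein and integrated stress response had medians of -0.09 in U251 and -0.05 in LN-319, and 14 of 28 were lower in both lines. ASNS, the asparagine synthetase gene, differed by -1.23 in U251 and -0.05 in LN-319. The serine synthesis genes PHGDH and PSAT1 differed by -0.62 and -0.45 in U251 and by -0.02 and -0.17 in LN-319. CHAC1, which degrades glutathione, differed by -0.39 and -0.31. The camera adjusted p for the list was 0.0435, and it was 0.832 with an estimated correlation. The list also missed the threshold without the cell line as a block (adjusted p = 0.114), without the filter on dim probe sets (adjusted p = 0.0815), with the median of all probe sets (adjusted p = 0.11) and with the interferon list left out (adjusted p = 0.0531).

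Among single genes, those with the largest differences of 1 sign in both lines were modest in size. Higher in both were RGS7, a regulator of G-protein signalling (0.57 in U251 and 0.73 in LN-319), TMEM154 (0.90 and 0.55), the receptor phosphatase PTPRG (0.58 and 0.53) and GRIK2, a kainate receptor subunit (0.98 and 0.52). SGK1, a kinase induced by glucocorticoids, was 0.64 and 0.46 higher, and the fatty acid binding protein FABP4 was 0.47 and 0.74 higher. The transcription factor genes HOXC8 and ZIC2 had mean differences of 0.52 and 0.52, PROC, PAQR3 and CHST9 of 0.52, 0.48 and 0.49, and the antisense gene PDCD4-AS1 of 0.52. Lower in both were TMEM200C (-0.87 and -0.65), CADPS, a factor for vesicle exocytosis (-1.26 and -0.64), the retinoic acid receptor RARB (-0.66 and -0.64) and NDRG1 (-0.85 and -0.60). OAS1, an interferon-induced synthetase, differed by -0.79 in U251 and by -2.87 in LN-319. Its U251 sh-Circ-SHPRH reading was below the array median. The other OAS genes of the interferon list, OAS2, OAS3 and OASL, differed by -0.02, 0.13 and 0.04 in U251. ZNF521, SOSTDC1, BEND5, ASPHD1, TSLP, GSDMB and CXCL3 had mean differences between -0.60 for CXCL3 and -0.52 for TSLP. Many of these rest on dim readings: RGS7, CHST9, PDCD4-AS1, CADPS, ZNF521 and CXCL3 read below the array median on 3 of the 4 arrays, FABP4 and PROC on both U251 arrays, and ZIC2, TMEM200C, RARB, SOSTDC1 and TSLP on both LN-319 arrays.

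No gene passed the shared test. limma gave 0 of 13471 genes at an adjusted p under 0.05, and the lowest adjusted p was 0.89. At an unadjusted p under 0.05 there were 648 genes, 323 higher and 325 lower, where chance gives 674. The count was also 0 without the line block and with a trended and robust prior. At least 2-fold differences in 1 direction in both lines were found for 0 genes higher and 0 genes lower. The named genes above therefore carry no call as single genes, and 0 list members passed when adjusted over the list alone.

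**Figure D1:**
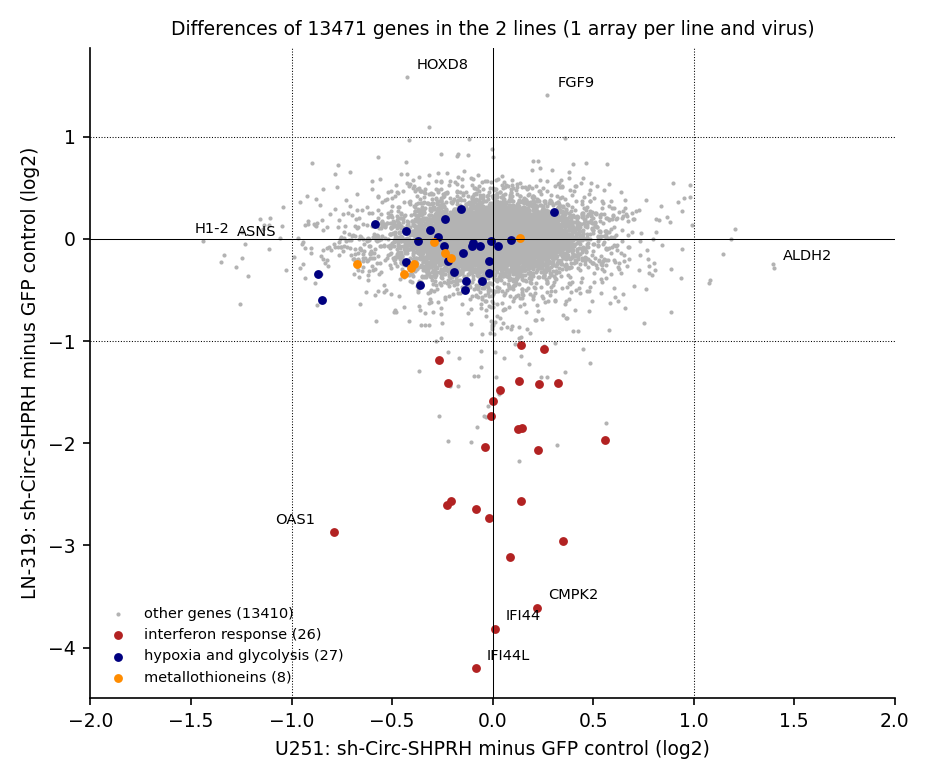
Each point is 1 of 13471 genes, with its sh-Circ-SHPRH minus GFP control difference in U251 on the horizontal axis and in LN-319 on the vertical axis (both log2, 1 array per line and virus); dotted lines mark 2-fold. The 26 interferon-response genes (red) lie below -1 in LN-319 and around 0 in U251, and no gene lies beyond 2-fold in the same direction in both lines.

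The responses of the lines were then set against each other across genes. Over the 13471 genes, which are not independent replicates, Pearson's r was 0.012 and Spearman's rho 0.042, and 50.6% of genes had the same sign in both lines. The lines share no array, so a shared control does not enter these values. At a 1.5-fold threshold 5 genes were lower in both lines, against 2 for independent lists. These were OAS1, TMEM200C, CADPS, RARB and NDRG1. Of these, TMEM200C, CADPS and RARB read below the array median on both LN-319 arrays, and OAS1 on the U251 sh-Circ-SHPRH array. At that threshold 0 genes were higher in both, against 0.31 for independent lists. In opposite directions 4 genes were higher in U251 and lower in LN-319, against 1.2, and 4 were lower in U251 and higher in LN-319, against 0.54. Within a line the differences had some structure: for 3129 genes with 2 separate probe sets, the differences read by the probe sets correlated at r = 0.336 in U251 and r = 0.48 in LN-319. Across the lines the same comparison gave 0.007 and 0.039. Without the interferon list, over 3122 genes, the values were 0.339 in U251, 0.332 in LN-319 and 0.02 in both comparisons across the lines.

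Some genes differed in opposite directions. LEMD1 differed by 0.75 in U251 and -0.83 in LN-319, POF1B by 0.89 and -0.72, and SYNDIG1 by 0.66 and -0.67. LAMP3, a lysosomal membrane protein, differed by 0.62 and -0.61. ANKRD1, a target of YAP signalling, differed by -0.90 in U251 and 0.74 in LN-319, and the decoy receptor IL13RA2 by -0.78 and 0.63. SLCO5A1 differed by -0.71 and 0.65, and the noncoding VHRT by -0.77 and 0.73. These genes were chosen for their opposite signs and were dim in at least 1 line: POF1B, LAMP3 and SLCO5A1 read below the array median on both U251 arrays, SYNDIG1, IL13RA2 and VHRT on both LN-319 arrays, and LEMD1 and ANKRD1 on at least 1 array. Whether the lines differed in these responses was not tested, since an interaction leaves no residual degrees of freedom.

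The second comparison was within U251. Among the genes with large positive differences was ALDH2, the mitochondrial aldehyde dehydrogenase, at 3.40 log2 in the control and 4.80 in the sh-Circ-SHPRH array (2.64-fold). MIPOL1 was 2.63-fold higher, the ephrin receptor EPHA5 2.31-fold, the transcription factor PROX1 2.27-fold and the matrix protein THBS2 2.21-fold. ATP8B3, the chemokine CCL20 and the gap junction gene GJA3 were 2.12-fold, 2.11-fold and 1.99-fold higher. The linker histone gene H1-2 had the largest negative difference, from 9.11 to 7.67 log2 (2.71-fold), followed by the protease inhibitor CSTA (2.55-fold lower) and the sialyltransferase ST6GAL1 (2.53-fold lower). ZNF542P, CADPS, ZNF502, GNRH1 and ASNS were between 2.42-fold (ZNF542P) and 2.35-fold (ASNS) lower. CCL20 and ZNF502 read below the array median on both U251 arrays, and ALDH2, MIPOL1, ZNF542P, CADPS and GNRH1 on 1 of them, so the sizes and order of these differences are uncertain.

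In U251 7 genes were at least 2-fold higher and 19 at least 2-fold lower. The SD of the differences over all tested genes was 0.21 log2, against 1.14 for the difference between the lines. With 64 added to the linear values, which compresses low levels, these counts were 0 and 3. With the median of all probe sets of a gene they were 4 and 10.

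Several lists had medians outside the central range of the random lists in U251 but inside it in LN-319. Whether the lines differed in these lists was not tested, and some members moved the same way in both lines. The 18 tested genes of cholesterol synthesis had a median of -0.22 in U251 (percentile 0 of 10000 random lists) and 0.08 in LN-319; 16 were lower in U251, among them MSMO1 (-0.38), HSD17B7 (-0.32), SQLE (-0.29) and SREBF2 (-0.34), of which SREBF2 was also lower in LN-319 (-0.21). Replication-dependent histones (7 genes) had a median of -0.30 in U251, with H1-2 at -1.44, H1-4 at -0.53 and H2BC5 at -0.30 but H4C8 at 0.23. In LN-319 the histone median was 0.07. The list for NRF2 and oxidative stress had medians of -0.14 and 0.02, with ME1, the malic enzyme, at -0.74 in U251 from readings below the array median. Oxidative phosphorylation had medians of -0.09 and 0.00, with 22 of 27 genes lower in U251. Targets of p53 were higher on balance in U251, 15 against 6 lower, at a median of 0.12 against -0.01 in LN-319. RRM2B was at 0.43 and GDF15, which read below the array median on both U251 arrays, at 0.51 but the death receptor FAS at -0.29. In LN-319 RRM2B, GDF15 and FAS were at 0.08, 0.13 and -0.51. ZMAT3 was 0.20 higher in U251 and 0.385 higher in LN-319. Extracellular matrix and mesenchymal genes had medians of 0.10 and 0.01, with THBS2 at 1.15 and FN1 at 0.51 in U251 but the crosslinking enzyme LOX at -0.85. In LN-319 THBS2, FN1 and LOX were at -0.15, 0.395 and -0.34, so FN1 and LOX moved the same way in both lines. None of these lists passed camera over both lines, with adjusted p of 0.156 for cholesterol synthesis, histones, oxidative phosphorylation and matrix genes and 0.417 for the p53 and NRF2 lists. Single alternatives gave a call: histones (adjusted p = 0.0153) and cholesterol synthesis (adjusted p = 0.0356) with the filter at the 75th percentile, and oxidative phosphorylation (adjusted p = 0.0258) with 64 added to the linear values. Over the alternatives the highest adjusted p was 0.832 for histones and oxidative phosphorylation and 0.858 for cholesterol synthesis.

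The U251 differences also followed chromosome regions, which were examined after the gene values had been seen. These region values used only genes with a mean level of at least 6 log2 and left out the interferon list. For the break tests and the neighbour correlations, differences beyond 2-fold were cut to 2-fold. Genes of chromosome 13 were higher in the sh-Circ-SHPRH array, with a median of 0.20 over 173 genes, 88.4% of them higher, while in LN-319 the median was 0.04. Genes of chromosome 3 had a median of -0.09 over 523 genes. On chromosome 2 the first 223 genes, up to MOB1A, had a median of 0.14 and the remaining 386 a median of 0.04. On chromosome 4 the first 85 genes, up to UCHL1, had a median of -0.16 and the other 229 a median of 0.05. On chromosome 6 the last 240 genes, from CDC5L on, had a median of 0.12 against -0.02 before. These 3 breaks each had an adjusted p = 0.0057 in a permutation test that shuffled gene order; the unadjusted p of 0.001 is the smallest the shuffles can give. Of 46 tests, 9 breaks in U251 and 4 in LN-319 had an adjusted p under 0.05. The LN-319 break on chromosome 11 fell next to TRIM22, an interferon-induced gene outside the fixed list. Such genes had not been left out, and their part in the LN-319 region values was not tested. SHPRH lies in the chromosome 6 part, and its 20 nearest genes had a U251 median of 0.13, with 16 of them higher. Across 8894 genes the difference of a gene and the mean of its 10 neighbours correlated at rho = 0.266 in U251 and 0.094 in LN-319, where the highest shuffled values were 0.04 and 0.057.

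**Figure D2:**
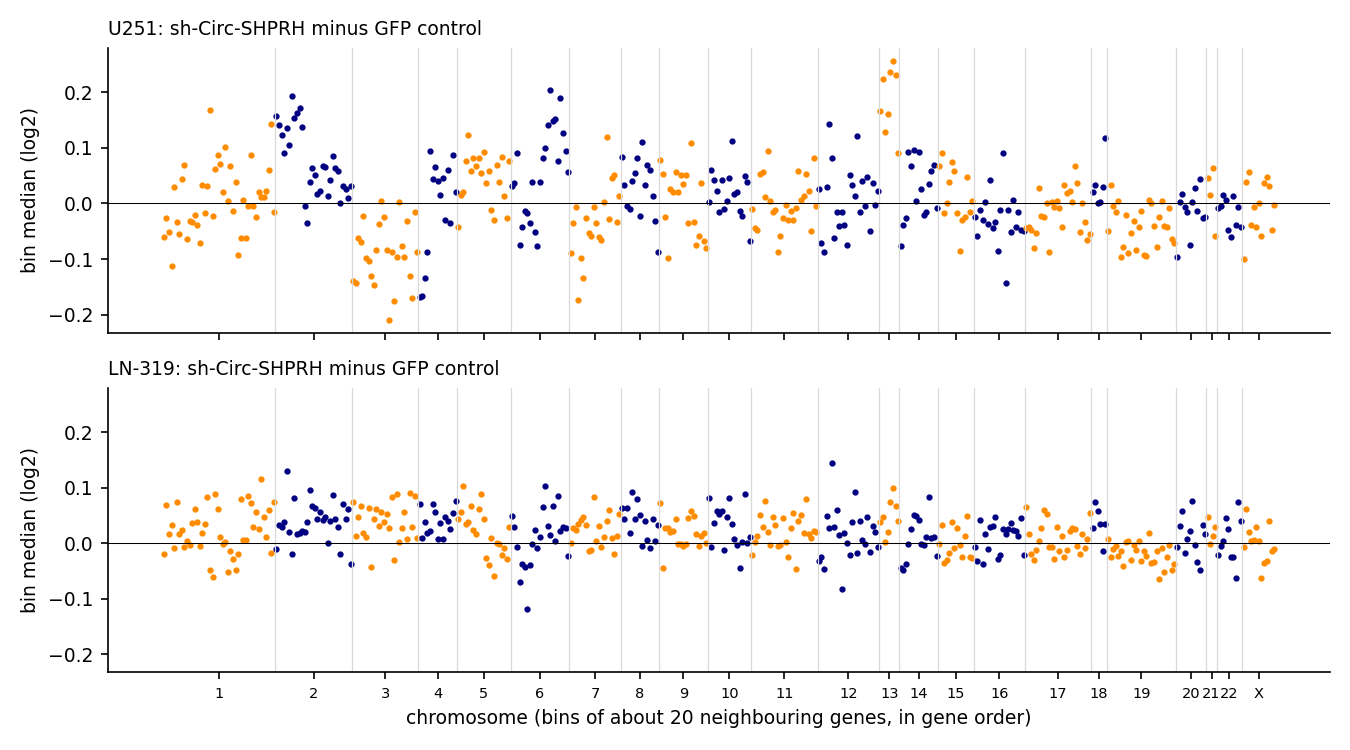
Median sh-Circ-SHPRH minus GFP control difference (log2, vertical axis) of runs of about 20 neighbouring genes, in gene order along the chromosomes (horizontal axis; colours alternate by chromosome), for U251 (top) and LN-319 (bottom). Only genes with a mean level of at least 6 log2 outside the interferon list are included. In U251 the runs of chromosome 13 lie above 0 (median 0.20 over these genes) and most of chromosome 3 below (median -0.09). Chromosomes 2, 4 and 6 step from 1 level to another.

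The third comparison was within LN-319, where interferon-response genes were lower in the sh-Circ-SHPRH array. All 26 tested members of the list were at least 2-fold lower, with a median difference of -2.01 (4.02-fold). IFI44L differed by -4.20 (18.4-fold), from 7.52 log2 in the control to 3.32, a reading below the array median, so the size of this difference is uncertain. IFI44 was 14.1-fold lower, the nucleotide kinase CMPK2 12.2-fold, the antiviral GTPase MX2 8.67-fold, XAF1 7.75-fold, the synthetases OAS1 and OAS2 7.31-fold and 6.65-fold, and MX1 6.26-fold. In U251 the same 26 genes had a median difference of 0.06, and 15 were higher and 10 lower.

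The 4 arrays differed in the level of these genes. Their median was 5.55 log2 in the U251 control, 5.57 in the U251 sh-Circ-SHPRH, 9.29 in the LN-319 control and 7.06 in the LN-319 sh-Circ-SHPRH array. Each of the 26 was highest on the LN-319 control array. The LN-319 sh-Circ-SHPRH array was above the mean of the U251 arrays by a median of 1.36, with 20 of the 26 higher there. Over both lines the list passed camera (adjusted p = 3.29e-10), although the difference was in 1 line; the adjusted p = 0.832 with an estimated correlation. The 3' minus 5' signal of ACTB was 3.94 on the LN-319 control and 4.17 on the LN-319 sh-Circ-SHPRH array.

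**Figure D3:**
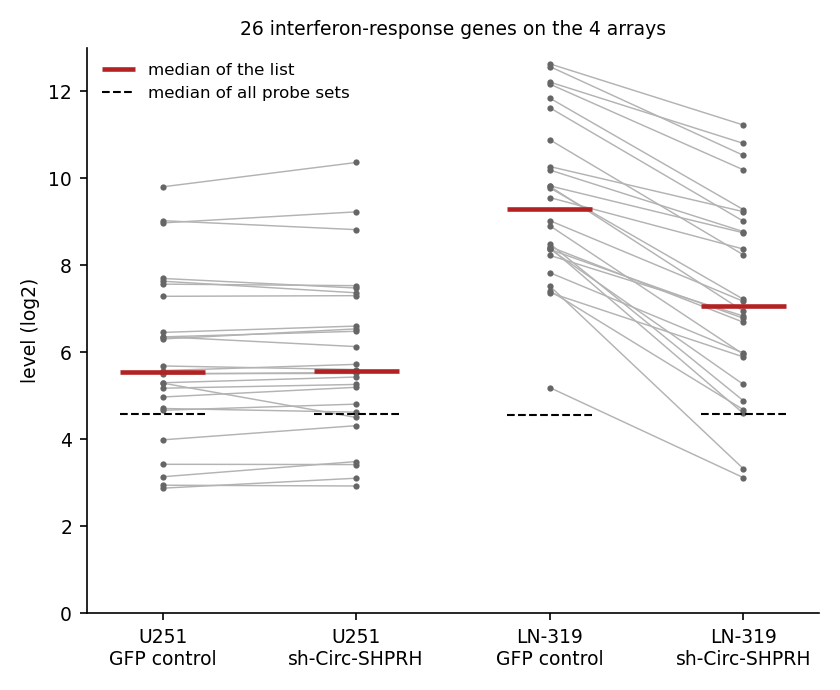
Log2 level (vertical axis) of the 26 interferon-response genes on the 4 arrays, with a grey line joining each gene's values within a line, a red bar at the list's median and a dashed bar at the median of all probe sets. The list's median is 9.29 on the LN-319 GFP control array, 7.06 on the LN-319 sh-Circ-SHPRH array, and 5.55 and 5.57 on the U251 arrays.

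In LN-319 3 genes were at least 2-fold higher and 60 at least 2-fold lower. Of the 60, 26 belonged to the interferon list and 34 did not. The 34 are not all outside the interferon response, since the fixed list lacks some interferon-induced genes. A further 22 such genes, chosen after the data were seen, had an LN-319 median of -1.35. Among them DDX60, EPSTI1, SAMD9L and GBP1 were each over 2-fold lower. The 3 higher genes were the homeobox gene HOXD8, from 3.15 to 4.73 log2 (2.99-fold), the growth factor FGF9, from 2.80 to 4.20 (2.65-fold), and the noncoding MIR924HG, from 4.33 to 5.43 (2.14-fold). In the lysosome and autophagy list, BECN1 was 1.74-fold higher. EID3, TOGARAM2, FRZB, KCNMB2 and PTPN5 were between 1.98-fold (EID3) and 1.78-fold (PTPN5) higher. FGF9 and EID3 read below the array median on both LN-319 arrays, and HOXD8, MIR924HG and PTPN5 on the control array, so the sizes and order of these differences are uncertain. The ectonucleotidase NT5E, in the list of YAP and TEAD targets, differed by -1.05, while CCN2, another target, differed by 0.82. NT5E read below the array median on the sh-Circ-SHPRH array, so the size of its difference is uncertain. With 64 added to the linear values the counts were 0 higher and 36 lower.

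The cell cycle lists differed little. The 30 genes of G2/M and mitosis had a median of 0.03 in U251 and 0.09 in LN-319, with TTK at 0.28 and 0.12, KIF11 at 0.17 and 0.17, HMMR at 0.20 and 0.12 and CENPF at 0.07 and 0.21. The LN-319 median was at percentile 99.9 of the random lists, and camera gave an adjusted p = 0.105 over both lines, with a range over the alternatives from 0.0154 with 64 added to the linear values to 0.832 with an estimated correlation. The 32 genes of G1/S and DNA replication had medians of 0.00 and 0.03, with CCNE2 at 0.32 and 0.16 but TK1 at -0.46 and 0.00. Notch pathway genes had medians of 0.04 and 0.11, with HEY2 at 0.32 in both lines. Immediate early genes had medians of 0.05 and 0.08 (FOSL2 at 0.59 and 0.19, JUN at 0.27 and 0.18), and YAP and TEAD targets 0.08 and 0.07. The Notch and immediate early medians lay outside the central 95% of random lists in LN-319.

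The remaining lists had these medians. They were -0.03 and -0.05 for NF-kB and inflammatory cytokines, 0.07 and -0.06 for apoptosis regulators, -0.07 and 0.07 for TGF-beta targets and 0.08 and -0.08 for glial and neural progenitor genes, each in U251 and LN-319 in that order. They were -0.01 and 0.08 for MYC targets and ribosome biogenesis, -0.08 and 0.08 for lysosome and autophagy, 0.02 and 0.07 for the small RNA processing machinery and -0.03 and 0.01 for housekeeping reference genes. Of these, lysosome and autophagy lay outside the central 95% of random lists in U251, with 17 of 23 genes lower, and MYC targets lay outside it in LN-319. Apoptosis regulators lay on its edge in LN-319, at percentile 2.42. They were counted as inside because their median and the bound, when rounded, were both -0.056. Markers of other cell types gave 0.05 and -0.07 for epithelial cells, 0.00 and -0.03 for blood cells and microglia, -0.15 and -0.13 for endothelial cells, -0.07 and -0.06 for neurons and -0.01 and -0.01 for oligodendrocytes. Of the 29 lists, 0 passed with an estimated correlation or with fry, which could hardly call any list with 1 residual degree of freedom. At the preset correlation 4 passed camera. The lowest adjusted p among the other 25 lists was 0.0919, for endothelial markers, with a range over the alternatives from 0.0378 with the median of all probe sets to 0.832 with an estimated correlation. The medians lay outside the central 95% of random lists for 10 lists in U251 and 8 in LN-319, and 14 lists were inside in both.

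**Figure D4:**
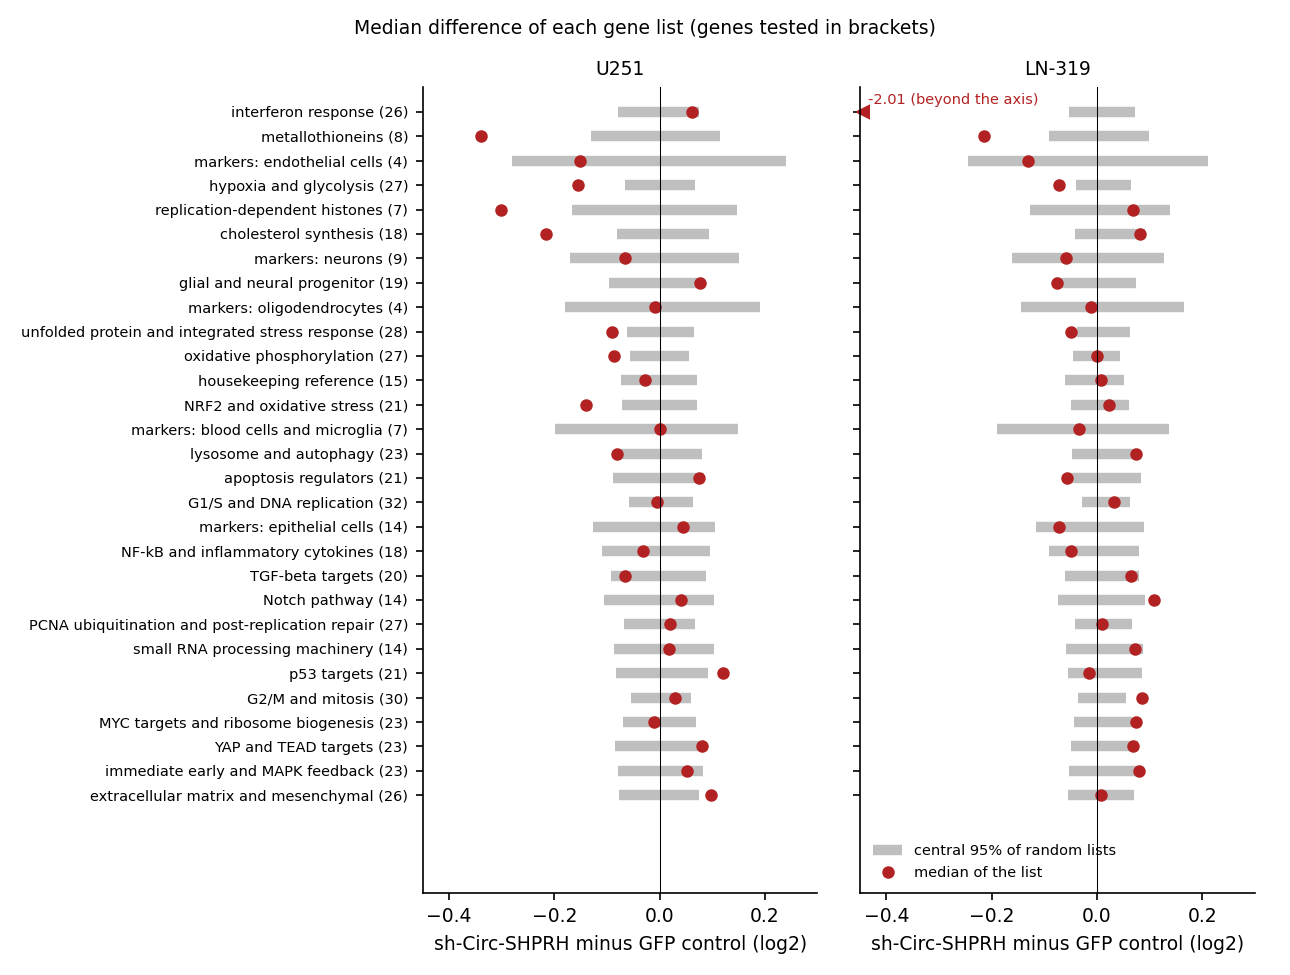
Median sh-Circ-SHPRH minus GFP control difference (log2, horizontal axis) of each of the 29 gene lists (vertical axis, genes tested in brackets) in U251 (left) and LN-319 (right); grey bars span the central 95% of 10000 random lists matched on expression. The hypoxia, metallothionein and stress response lists lie below the grey bar in both lines, and the interferon list lies at -2.01 in LN-319, beyond the axis.

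The last comparison asked how far the lines differed whatever the virus. LN-319 expressed the neuropeptide somatostatin SST (9.75 log2 higher than U251), the Notch-like protein DLK1 (9.62), the cancer-testis antigens MAGEA6 (9.03) and MAGEA12 (8.28), ALDH1A1 (8.47) and PERP (8.26), all of which read below the array median on both U251 arrays. U251 expressed the glutathione transferase MGST1 (LN-319 minus U251 -9.01), EDIL3 (-8.83), ERRFI1 (-8.58), PARK7 (-8.36), SEMA3C (-8.04) and AKR1B10 (-7.84), of which AKR1B10 read below the array median on 1 LN-319 array and the others on both. The exact sizes and order of all these differences rest on such dim readings and are uncertain. PARK7 read 11.4 log2 on both U251 arrays and 3.47 and 2.66 on the LN-319 arrays. ERRFI1, on the same chromosome 1, read 11.3 and 11.4 in U251 and 2.75 and 2.76 in LN-319. limma called 7212 of 13471 genes different between the lines, 3645 higher and 3567 lower in LN-319; 2397 of them differed at least 2-fold. The adjusted p was 1.36e-04 for SST and MGST1. These p-values compare 2 arrays of each line and treat the virus arrays of a line as its replicates.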

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

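The lists and genes here went in opposite directions in the lines, or came from probe sets outside the gene-level comparison; the differences between the lines were not tested, because 1 array per line and virus leaves no residual degrees of freedom. Of the tests below, those of spike-in controls, of a fall common to both lines and of the control culture were chosen after the interferon result was seen, and the test of mixed cells was chosen before its result was seen.

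In 8 lists the medians had opposite signs in the lines and at least 1 line lay outside the central 95% of random lists. The LN-319 median minus the U251 median was -2.07 for the interferon response, 0.37 for replication-dependent histones, 0.30 for cholesterol synthesis, 0.16 for NRF2 and oxidative stress, 0.16 for lysosome and autophagy, 0.09 (0.088) for oxidative phosphorylation, 0.09 (0.085) for MYC targets and ribosome biogenesis and -0.14 for p53 targets.

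Opposite signs were also seen in the 8 genes named for the largest opposite differences. The LN-319 difference minus the U251 difference was -1.58 for LEMD1, -1.60 for POF1B, -1.33 for SYNDIG1 and -1.23 for LAMP3. It was 1.64 for ANKRD1, 1.36 for SLCO5A1, 1.42 for IL13RA2 and 1.49 (1.494) for VHRT.

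Outside the gene-level comparison, 5363 probe sets without a single gene symbol were at or above the array median on at least 1 array. Of these 11 were at least 2-fold lower and 0 at least 2-fold higher in the LN-319 sh-Circ-SHPRH array. In U251 7 were lower and 2 higher by that size, and 0 were in both lines.

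For the interferon genes of LN-319, array-wide scaling could hardly show, since the arrays had been brought to nearly the same distribution before deposit. The median of the 21 spike-in control probe sets differed by 0.05 log2 (0.047) between the LN-319 arrays, which for the same reason decides little. U251 cells mixed into the LN-319 sh-Circ-SHPRH culture are argued against by 15 genes high in U251 and dim in LN-319: their median difference was 0.004, where the 75.1% of U251 cells needed would give 7.04. A fall common to both lines is argued against by 12 list members at least 1 log2 above the array median in U251, whose median difference there was -0.01 (-0.011). What stays open is whether the LN-319 control culture was in an interferon state that does not depend on the circular RNA: 26 of 26 genes were highest on that array, and a knockdown effect in LN-319 predicts the same. The knockdown effect is the biological explanation the design gives; with 1 culture per line and virus it cannot be told apart from a difference between cultures.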

How the results depend on the processing

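Leaving out the interferon list and subtracting neighbouring genes were chosen after the data were seen; the other alternatives were set beforehand. The count of 0 genes passing the shared test held under all alternatives run, as did 0 genes at least 2-fold higher in both lines; unadjusted p-values under 0.05 ranged from 1 without the line block to 872 without the filter. The correlation between the lines stayed between 0.004 and 0.038, and genes differing between the lines numbered 5970 to 7625.

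Counts by size moved as follows. At a 1.5-fold threshold they were 98 higher and 170 lower in U251, 43 and 162 in LN-319, and 5 lower in both lines. With log2(linear value + 64), which shrinks differences of dim genes by construction, they were 0 and 3 in U251 and 0 and 36 in LN-319. With the median of all probe sets U251 had 4 and 10, and with the filter at the 75th percentile, where fewer genes were tested, 9 lower; the cause of the former was not tested. Subtracting neighbouring genes gave 8 and 23 in U251.

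The 4 list calls became 0 with an estimated correlation and 0 with fry, and 2 with the interferon list left out. Other settings gave 3 to 6. The estimated-correlation test rests on 1 residual degree of freedom and could hardly call any list. Without the line block, the pairing of arrays by line, 0 genes and 3 lists passed; the block changed no call other than that of the stress response list. Over the alternatives the adjusted p ranged from 2.58e-08 to 0.832 for hypoxia, from 2.59e-07 to 0.868 for metallothioneins, from 0.00903 to 0.832 for the stress response and from 1.5e-12 to 0.832 for interferon genes. Over lists and alternatives, 5 results gained a call (histones and cholesterol synthesis at the 75th percentile, endothelial markers with the median of probe sets, G2/M and oxidative phosphorylation with 64 added), 13 lost it, 15 had the other direction in the test with no call on either side, and 283 kept direction and side. With a line left out no residual degrees of freedom remain, so only values could be given. Of 48 such values for shared genes, 8 moved by more than the spread over genes. These genes were chosen for differences of 1 sign in both lines, which by itself favours small moves. Of the single-line values of all named genes, 179 moved by more than the SD of that line's differences and 2169 did not. Of the 179, 126 moved with 64 added and 50 with the median of all probe sets. At the 75th percentile the blood cell and endothelial marker lists had too few genes for a value. Dim signal is 1 limit on the counts by size, as the counts with 64 added show; the limits were not ranked.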

Other observations

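The gene groups of the next 2 paragraphs were chosen after the data were seen, as were the tests of a property alike in all array pairs, of metallothionein and stress response genes against their neighbours, and of culture conditions. The tests of copy number, of base composition, of a random draw and of the hypoxia list against its neighbours were chosen before their results were seen.

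Beyond the interferon list, antigen presentation genes were lower in the LN-319 sh-Circ-SHPRH array. All 16 tested genes were lower there, with a median of -0.59, while 12 of them were higher in U251, where the median was 0.14. TAP1, a peptide transporter, was 2.11-fold lower in LN-319 and 1.36-fold higher in U251, and the immunoproteasome subunit PSMB9 was 2.21-fold lower and 1.10-fold higher. HLA-B, HLA-C and HLA-E, read by _x_at probe sets, were 1.67-fold, 1.63-fold and 1.74-fold lower in LN-319. A further 22 interferon-induced genes outside the fixed list had a median of -1.35 in LN-319 and -0.02 in U251; DDX60 was 4.05-fold, EPSTI1 4.51-fold and SAMD9L 3.98-fold lower in LN-319, where EPSTI1 and SAMD9L read below the median of the sh-Circ-SHPRH array, so their sizes are uncertain. The interferon receptor genes IFNAR1 and IFNAR2 differed by 0.13 and -0.17 in LN-319, and the receptor kinases JAK1 and TYK2 by 0.09 and 0.05.

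Genes of chromosome 19 were lower on balance in the sh-Circ-SHPRH arrays of both lines. In U251, of its 161 zinc finger genes 108 were lower, with a median of -0.07, and of its 807 other genes 482 were lower, with a median of -0.04. In U251 differences of at least 1.5-fold lower were found in 20 of the 161 zinc finger genes, in 5 of the 807 others and in 3 of 204 zinc finger genes on other chromosomes. ZNF788P, ZNF83 and ZNF677 were 2.16-fold, 2.08-fold and 2.06-fold lower in U251, and ZNF91 1.89-fold; ZNF677 and ZNF91 read below the median of the U251 sh-Circ-SHPRH array, so their sizes are uncertain. In LN-319 84 of the 161 zinc finger genes were lower, with a median of -0.02, and 469 of the 807 others, with a median of -0.02; 1 and 7 of these were at least 1.5-fold lower.

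The chromosome pattern of U251 may reflect a different copy number between the cultures, a hypothesis for which no DNA was analysed here. In its test the 86 dimmer of the 173 chromosome 13 genes shifted by 0.22 (0.216) and the 87 brighter by 0.18. These differ by no more than 2 bootstrap SE of 0.03 (0.026), as a copy number change predicts. All 173 had a mean level of at least 6 log2, above the array medians, so genes below those medians were not covered. For chromosome 13, a probe or annotation property of like size in every array pair is argued against by the LN-319 median of 0.04. For other chromosomes it stays open. In LN-319 5 chromosomes lay outside the central 95% of random lists. Chromosomes 2, 8, 17 and 19 lay there on the same side as in U251, and chromosome 3 on the other side. Chromosomes 4 and 13 lay on the edge in LN-319, at percentiles 97.66 and 97.82. They were counted as inside because their medians and the bounds, when rounded, were equal. Chromosome 13 lay on the same side in U251, so a shared property of smaller size stays open there too. Base composition acting on 1 array stays open, since 0% of genes had a GC value in the tables used and that test is void. An effect of the hairpin on these regions also stays open, as it was not tested.

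The lower hypoxia, metallothionein and stress response lists could be a random draw. Of 1000 simulated sets of 29 random lists, 0 had 3 lists outside the central 95% in 1 direction in both lines. Leaving aside the metallothioneins, whose probe sets overlap, 2 of 1000 sets had as many as the other 2 lists. However, the simulated lists held unrelated genes. Of the real lists, 10 in U251 and 8 in LN-319 lay outside, more than random lists give. The simulation therefore cannot decide whether 3 shared lists exceed what lists of related genes give by chance. The U251 chromosome regions are argued against as the cause: with neighbouring genes subtracted the U251 medians were -0.15 (-0.154) for hypoxia, -0.30 (-0.302) for metallothioneins and -0.08 (-0.077) for the stress response. The metallothionein value was -0.22 when other metallothioneins counted as neighbours, and leaving them out was chosen after that value was seen. Culture conditions that differed between the GFP and sh-Circ-SHPRH flasks stay open beside the knockdown and cannot be told apart from it with 1 array per line and virus.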
